A study of Zymomonas mobilis subsp. mobilis ZM4 = ATCC 31821 with 18 samples.

How the data were processed

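RNA-seq was carried out on Zymomonas mobilis ZM4 grown in RM medium with 20 g/L glucose, in standing cultures at 30 °C, per the labels' protocols. There were 18 libraries in 6 groups of 3, formed by 2 plasmids and 3 phenolic aldehydes, and each library was put in its group by its label. Total RNA was isolated with TRIzol, per the labels' protocols, which list the molecule as polyA RNA, an unusual entry for a bacterium. The doses of the aldehydes, the time of harvest, the library kit's strandedness, the aligner and its settings are not given in the sources used here. HTSeq is the counting tool named in the submitters' processing notes, without a version.

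The authors deposited raw read counts per gene and per transcript, 1 column per library, per the file headers. The authors also deposited FPKM values per gene, and division of the gene counts by gene length gave 1 constant per library, so the FPKM values hold the same counts scaled to length and to the counted reads of the library. The 6 libraries under 4-hydroxybenzaldehyde had tables of their own, and the 12 libraries under syringaldehyde and vanillin shared tables. The tables hold 1758 genes and 1760 transcripts, with positions on the ZM4 chromosome as printed in the tables, and 7 rRNA genes are among them. Of the 1758 genes, 673 carry a symbol and 444 overlap a neighbouring gene, so that their reads can be split or lost by the counting. Gene names were taken from the tables; 1721 identifiers also matched the RefSeq names of assembly ASM305457v1, which was used for names only. The transcript tables hold about 3.9 times the counts of the gene tables (median ratio 3.89 over 1739 genes), for a reason that is not given in the sources used here. Transcript-level FPKM values were not used here.

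Gene counts summed to between 7519008 and 12745415 per library. A floor of 3 counts in a library corresponded to between 0.235 and 0.399 CPM, the counts scaled to a common library total, and such floors cover counting error only, because reads without molecular identifiers are not independent molecules. Replicate pairs of a group differed by far more than sampling noise (chi-square per degree of freedom between 6.02 and 683, Pearson r of log values across genes between 0.952 and 0.998), so no library was treated as a copy of another. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

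Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test after TMM normalization and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. The libraries under 4-hydroxybenzaldehyde were fitted alone (1750 genes), and the 12 libraries under the other aldehydes were fitted together as 4 groups (1755 genes). Differences between the strain effect under 4-hydroxybenzaldehyde and that under another aldehyde were tested in a fit of all 18 libraries, because levels under 4-hydroxybenzaldehyde cannot be compared directly with levels in the other set of tables. CPM values in the text use the TMM-scaled library sizes of these fits and are given as mean ± SD with n = 3. The standard error of a log2 fold change was taken from the F statistic, and 95% intervals of differences from the quasi-likelihood degrees of freedom. Adjusted p-values in the text are from edgeR unless another tool is named. Exact two-sided permutation tests of 3 against 3 libraries cannot give a p below 0.1.

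Gene lists (27, from product descriptions, symbols and locus tags) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, for the 26 lists with at least 4 tested members. Fry was not used here to call any list, whatever its p values, because these shifted with the order of the groups in the design. With that order reversed, 3 of 208 mixed p values moved to the other side of 0.05 (1 when adjusted) and none of the directional ones, with shifts of up to 10.93-fold and 2.259-fold, while no camera p value shifted. They covered the Entner-Doudoroff and ethanol pathway, aldehyde and alcohol oxidoreductases, ribosomal proteins, aminoacyl-tRNA synthetases, translation and RNA polymerase factors, amino acid and nucleotide biosynthesis, sulfur and nitrogen metabolism, ATP synthase, the respiratory chain, hopanoid synthesis, fatty acids, the cell envelope, transport, efflux, iron uptake, flagella, stress responses, DNA repair, signalling, regulators, secretion and toxins, mobile elements, and 2 lists of RNA quality (rRNA, and abundant small RNAs). After the lists were matched to the annotation, ZMO1162 was left out of the signalling list. The annotation in the tables, L-threonine dehydrogenase, contradicted the name of 1 locus tag, ZMO1596, which was left out. Which name is right was not checked, so a list may lack this member. Enzymes that act on rRNA were removed from the rRNA list, also after the matching. Tests of annotation categories were not run, because the tables carry no column of such categories.

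The samples, the tests, the lists apart from the removals made after matching, all alternatives but the 3 named last and the rule for named genes were set before the data were examined. In the strain comparisons the rule took ZMO1162, a fixed set of genes (its neighbour phoU, pdc, adhP, ZMO1116, ZMO1696 and ZMO1885), the 8 genes with the largest change each way among those with adjusted p below 0.05, a mean of at least 10 CPM in the higher group and no overlap between the groups, and the 3 members with the smallest p of each list called by camera. In the other comparisons it took ZMO1162 and the 5 largest each way. The a priori neighbour ZMO1161 had no values in the tables used here. Genes named outside this rule are said to have been chosen after their values were seen.

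The replicate numbers of the labels were checked for pairing by correlating the deviations of same-numbered libraries from their group means across genes. Under syringaldehyde, all 3 same-numbered pairs of the 2 strains correlated at 0.117 to 0.199, above the limit of 0.1 set for pairing. The blocked result is given beside that comparison, but its block also tied the same-numbered libraries under vanillin. Same-numbered vector libraries of these 2 aldehydes correlated at -0.924 to 0.678. The blocked result is therefore not a test of pairing under syringaldehyde alone. In the other pairs of groups that were compared, at least 1 pair lay at or below the limit.

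The pipeline was tested on simulated counts for each comparison, in which 200 genes were changed by known folds, 50 per fold. For the strain effect under 4-hydroxybenzaldehyde (1750 genes) the test recovered 44% of genes changed 1.25-fold, 96% at 1.5-fold, 98% at 2-fold and 100% at 4-fold. For the strain effect under syringaldehyde (1755 genes) it recovered 12%, 60%, 86% and 98% at the same folds, and under vanillin (1755 genes) 10%, 54%, 86% and 100%. For the difference between syringaldehyde and vanillin (1755 genes) it recovered 2%, 24%, 62% and 96%, for 4-hydroxybenzaldehyde minus vanillin 6%, 40%, 80% and 100%, and for 4-hydroxybenzaldehyde minus syringaldehyde 6%, 40%, 80% and 98%. For syringaldehyde against vanillin it recovered 16%, 64%, 90% and 100% in the vector strain and 10%, 56%, 84% and 98% in the ZMO1162 strain. False calls made up 2.2% to 6.6% of calls. A simulated list of 50 genes raised 1.25-fold was called by camera in every comparison, with 0 of 26 unchanged lists called. In all these simulations each gene varied independently of the others, and no library stood apart. They therefore cannot show how often camera at the preset correlation falsely calls lists whose genes move together.

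Alternative settings were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter on low counts, an added threshold of 1 on the absolute log2 fold change, the replicate number as a block, transcript-level counts, limma-trend on log2(FPKM + 1) for genes with a mean of at least 1 FPKM, removal of rRNA and ZMO1162 before scaling, other sets of libraries in the fit, and omission of each library in turn. An analysis without vector syringaldehyde replicate 3 and vector vanillin replicate 1, voom with sample quality weights, and total counts alone without TMM factors were chosen after seeing the data. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.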

Results

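The transcriptome of Zymomonas mobilis ZM4, a bacterium that ferments glucose to ethanol through the Entner-Doudoroff pathway, was profiled in 2 strains under 3 phenolic aldehydes. One strain carried the empty plasmid pHW20a (the vector strain), and the other carried pHW20a with ZMO1162, a gene annotated as a two-component sensor histidine kinase (the ZMO1162 strain). The aldehydes are inhibitors released from lignin and differ by methoxy groups on the ring: 4-hydroxybenzaldehyde has none, vanillin has 1 and syringaldehyde has 2. Each of the 6 groups held 3 libraries, with 7519008 to 12745415 counts per library over 1758 genes. The title and design text of the series name the effect of kinase gene overexpression on the transcriptome, on aldehyde conversion and on ethanol production, and the RNA-seq libraries address the first of these. Each strain comparison asked which transcripts differed between the strains under 1 aldehyde, and the aldehyde comparison asked which differed between syringaldehyde and vanillin within a strain.

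ZMO1162 (chromosome positions 1177190 to 1178455, plus strand) was higher in every library labelled as carrying it. Under 4-hydroxybenzaldehyde its level, in CPM (counts scaled to a common library total), was 1000 ± 74.3 in the ZMO1162 strain against 44.9 ± 3.45 CPM in the vector strain (SD, n = 3 each), a 22.3-fold difference (log2 4.48, SE 0.10, adjusted p = 9.06e-09). Under syringaldehyde it was 891 ± 77.5 against 94.5 ± 28.6 CPM, 9.41-fold (log2 3.24, SE 0.24, adjusted p = 8.30e-05). Under vanillin it was 1005 ± 46.3 against 76.8 ± 23.9 CPM, 13.1-fold (log2 3.71, SE 0.25, adjusted p = 2.54e-05). The exact two-sided permutation test gave p = 0.1 for each aldehyde, the smallest p that 3 against 3 libraries allow. The 3 strain effects on ZMO1162 did not differ past the threshold when adjusted over all genes (adjusted p = 0.997 for syringaldehyde minus vanillin, 0.164 for 4-hydroxybenzaldehyde minus vanillin and 0.0721 for 4-hydroxybenzaldehyde minus syringaldehyde, edgeR). For this gene alone, the 95% intervals of both differences from 4-hydroxybenzaldehyde lay above 0. They were 0.779 log2 units (0.184 to 1.374) for vanillin and 1.224 (0.629 to 1.82) for syringaldehyde. Syringaldehyde minus vanillin was -0.472 (-1.173 to 0.229). These intervals include 2 vector libraries that stood apart from their groups, described below. Without them, a choice made after seeing the data, the log2 changes were 3.518 under syringaldehyde and 3.984 under vanillin. Both lie nearer to the value under 4-hydroxybenzaldehyde than with all libraries.

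**Figure D1:**
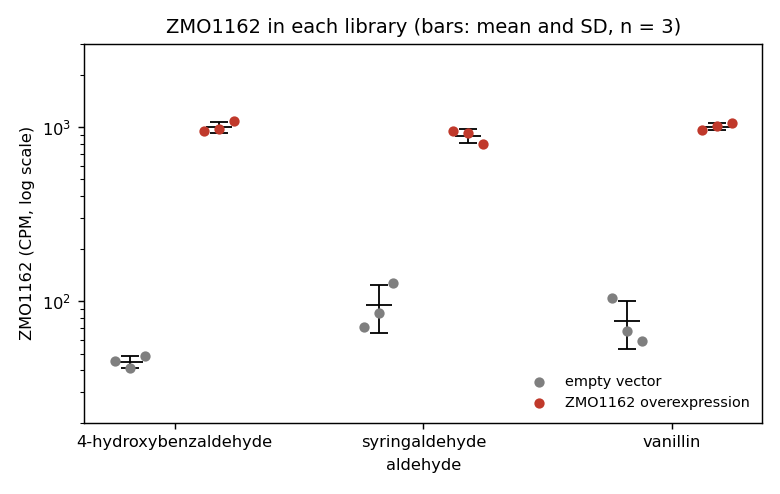
ZMO1162 in CPM (log axis) in each of the 18 libraries by aldehyde and strain, with mean and SD of 3 libraries. The lowest library of the ZMO1162 strain stood at 802.6 CPM and the highest vector library at 126.5 CPM, both under syringaldehyde.

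Under 4-hydroxybenzaldehyde, 432 genes rose and 364 fell in the ZMO1162 strain among 1750 tested, so that 45.49% were called. In all, 14 called genes changed at least 2-fold, ZMO1162 and 2 copies of 23S rRNA (ZMOr002, 20.1-fold, and ZMOr005, 3.59-fold higher) among them. After these 3, the largest rises were in ZMO0373 (2.43-fold), the amino acid racemase ZMO1158 (2.23-fold), the Lrp-type regulator zrp (ZMO0372, 2.09-fold), ZMO0768 (2.08-fold) and the N-formylglutamate amidohydrolase ZMO1181 (1.99-fold). ZMO1158 stood at 164 ± 39.2 against 73.5 ± 5.57 CPM (log2 1.16, SE 0.16, adjusted p = 0.00646). The signal peptidase ZMO1941, named after its values were seen, fell 3.82-fold at a low level (0.61 ± 0.45 from 2.33 ± 0.79 CPM). Of the falls among genes with at least 10 CPM, that of the DEAD/DEAH box helicase ZMO1417 was largest, to 363 ± 93.4 from 917 ± 97.9 CPM (log2 -1.34, SE 0.17, adjusted p = 0.00646). The next 7 were all ribosomal protein genes that lie together on the chromosome, between positions 517755 and 521538. Among them rplB fell to 1338 ± 515 from 2911 ± 341 CPM (2.18-fold), rpsS 2.11-fold, rplW 2.08-fold, rpsJ 2.01-fold, rplV 2.00-fold, rplC 1.98-fold and rplD 1.93-fold.

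Gene lists of protein synthesis and of amino acid biosynthesis were called as lower under 4-hydroxybenzaldehyde by camera at the preset correlation, and a list of signalling as higher. With an estimated correlation, none of these 4 lists passed (adjusted p = 0.679 for each). Of 57 genes listed as ribosomal proteins, 8 rose, 30 fell and 19 did not pass the test (camera adjusted p = 3.57e-04; 8 and 33 adjusted over the list alone). Among those that rose was rimI, an acetyltransferase that modifies a ribosomal protein (55.6 ± 4.92 against 36.3 ± 1.95 CPM). Of 63 amino acid biosynthesis genes, 5 rose and 30 fell (camera adjusted p = 5.35e-05; 6 and 34 adjusted over the list alone). Examples of falls were aroE (1.77-fold lower), dapB (1.65-fold) and ilvD (736 ± 108 against 1136 ± 41.0 CPM, 1.54-fold). Of 21 aminoacyl-tRNA synthetases, none rose and 10 fell (adjusted p = 0.00483; 12 adjusted over the list alone), with leuS 1.59-fold, gltX 1.52-fold and pheT 1.32-fold lower. Among 24 genes of two-component and signalling systems, 13 rose and 2 fell (adjusted p = 0.0298; the same counts adjusted over the list alone). These included the response regulator ZMO1387 (1.66-fold higher), the globin-coupled sensor ZMO0882 (1.61-fold) and the histidine kinase ZMO1216 (1.41-fold). The rRNA genes, kept as a sign of RNA quality, did not move together. Of 5 tested, ZMOr002 (12.7 ± 9.09 against 0.640 ± 0.421 CPM) and ZMOr005 (66.4 ± 32.1 against 18.5 ± 3.01 CPM) rose, ZMOr009 fell (log2 -0.63) and the other 2 were not called; the list's median was -0.44 and its mean 0.89. Both abundant small RNAs, rnpB (log2 -0.57, adjusted p = 0.00646) and ssrA (log2 -0.62, adjusted p = 0.0172), fell beside these gene groups.

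Among the genes of ethanol formation and aldehyde reduction, pdc, which encodes pyruvate decarboxylase, fell to 13138 ± 3438 from 21066 ± 1020 CPM (1.60-fold, SE of the log2 change 0.17, adjusted p = 0.0132). The alcohol dehydrogenase gene adhP stood at 12621 ± 304 against 10855 ± 293 CPM and was not called (adjusted p = 0.0648). Of 13 genes of the Entner-Doudoroff and ethanol pathway, 6 fell and none rose, also when adjusted over the list alone, but the list was not called (camera adjusted p = 0.106). Of the oxidoreductases set in advance, ZMO1116 fell 1.27-fold (adjusted p = 0.0161), while ZMO1696 (184 ± 15 against 168 ± 15.9 CPM) and the alkene reductase ZMO1885 (951 ± 86.3 against 1024 ± 23.5 CPM) were not called. Of 33 aldehyde and alcohol oxidoreductases, 3 rose and 10 fell (adjusted p = 0.239; 3 and 9 adjusted over the list alone). phoU, next to ZMO1162, stood at 359 ± 31.1 against 309 ± 16.1 CPM (adjusted p = 0.0606).

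The balance of rises and falls under 4-hydroxybenzaldehyde depended on scaling: with total counts alone, a setting chosen after seeing the data, 78.5% of 845 called genes were higher against 54.3% with TMM, limma on FPKM gave 78.1% of 826, and the median log2 change of all genes moved from 0.01 to 0.18. The count of 796 became 263, 375 or 525 without vector replicate 1, 2 or 3, 518 without ZMO1162 replicate 1 and 413 in the fit of all 18 libraries. Between the groups, 1083 genes (61.9%) had no overlap, against 10% by chance for 3 against 3.

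Under syringaldehyde, 7 genes rose and 4 fell in the ZMO1162 strain among 1755 tested. Beside ZMO1162, the rise was largest in ZMO1373 (918 ± 67.7 against 577 ± 85.3 CPM, 1.59-fold, adjusted p = 0.0339), followed by ZMO1892 (1.41-fold), the Fe-S binding protein ZMO0022 (1.39-fold) and ZMO1794 (1.38-fold). The YceI family protein ZMO1334 stood at 365 ± 14.2 against 265 ± 10.8 CPM (adjusted p = 0.0127). The aldo/keto reductase ZMO1344, of a family that reduces aldehydes, stood at 277 ± 10.9 against 208 ± 5.37 CPM (adjusted p = 0.0201). The glutathione reductase gene gorA fell 1.44-fold (178 ± 5.29 against 255 ± 20.7 CPM, adjusted p = 0.0201). The other falls were in ZMO1784, ZMO1785 and ZMO1782, which lie side by side and are described with the vanillin values. The other genes set in advance were not called. The level of pdc was 19242 ± 2028 against 17123 ± 6596 CPM (adjusted p = 0.869) and that of adhP 3005 ± 258 against 2300 ± 310.5 CPM (adjusted p = 0.365). ZMO1116, ZMO1696, ZMO1885 and phoU had adjusted p of 0.731, 0.264, 0.679 and 0.468.

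Vector syringaldehyde replicate 3 and vector vanillin replicate 1 stood apart from their groups (r of 0.958 and 0.968 with the others), and without them, an alternative chosen after seeing the data, 148 genes were called under syringaldehyde, 100 higher and 48 lower. With the replicate number as a block over the libraries of syringaldehyde and vanillin together (replicate block), 3 genes were called, ZMO1162, ZMO1784 and ZMO1785. The calls of ZMO1373, ZMO1892, ZMO0022 and ZMO1794 (adjusted p = 0.145 each), ZMO1334 (0.103), ZMO1344 (0.132), gorA (ZMO1211, 0.114) and ZMO1782 were lost there. DESeq2 called 49, voom with sample quality weights, chosen after seeing the data, 94, limma on FPKM 5 and a fit of only the 6 libraries compared 3. The count of 11 became 3, 6 or 6 without vector replicate 1, 2 or 3 and 3, 5 or 4 without ZMO1162 replicate 1, 2 or 3, and with total counts alone 2 of 5 calls were rises. Between the groups, 279 genes (15.9%) had no overlap, against 10% by chance.

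Gene lists showed few changes under syringaldehyde. Both lists called by camera lost the call with an estimated correlation (adjusted p = 0.869 for each). The Entner-Doudoroff and ethanol pathway was called as higher (adjusted p = 0.0163) although none of its 13 genes was called, nor when adjusted over the list alone. Of its members, zwf stood at 4484 ± 358 against 3621 ± 838 CPM and eda at 11008 ± 1384 against 8517 ± 2839 CPM. The rRNA list was called as higher (adjusted p = 0.0163), with none of 5 genes called over all genes and 2 adjusted over the list alone, and ZMOr005 stood at 102 ± 23 against 30.9 ± 20.9 CPM. Without the 2 libraries that stood apart their camera adjusted p was 0.694 and 0.305. In that analysis 1 of 57 ribosomal protein genes rose and 7 fell (adjusted p = 2.80e-05), and of 23 genes of sulfur assimilation and cysteine and methionine synthesis 1 rose and 2 fell (0.0333). Neither passed with an estimated correlation (0.767 for each). With all libraries, ZMO1344 was the only one called of the 33 aldehyde and alcohol oxidoreductases, and gorA the only one of 32 genes of oxidative stress and thiol redox. With the 2 libraries left out, 5 of the oxidoreductases rose and 1 fell, and 5 of the oxidative stress genes rose and 5 fell.

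Under vanillin, 29 genes rose and 21 fell in the ZMO1162 strain among 1755 tested. ZMO1754, annotated as an NAD-dependent succinate-semialdehyde dehydrogenase, rose to 2342 ± 78.6 from 1321 ± 92.5 CPM (1.77-fold, log2 0.83, SE 0.11, adjusted p = 0.00448). The 2-hydroxyacid dehydrogenase gene ldhA (ZMO1237) rose to 1151 ± 87.5 from 724 ± 95.3 CPM (1.59-fold, adjusted p = 0.0191). ZMO1373 (1.58-fold), the acyl carrier protein ZMO2012 (1.56-fold), the integration host factor subunit ZMO1801 (1.55-fold) and the transporter subunit ZMO0572 (1.53-fold) also rose. Besides ZMO1782, ZMO1784 and ZMO1785, which are described below, the largest falls were in rpsJ (743 ± 26.7 from 1215 ± 134 CPM, 1.64-fold, adjusted p = 0.0273), ZMO0139 (1.62-fold), rpsD (1.56-fold), tsaE (1.54-fold), ZMO1100 (1.53-fold) and ZMO1012 (1.47-fold). Except for ZMO1162, the genes set in advance were not called. Levels were 19494 ± 1345 against 16051 ± 6036 CPM for pdc (adjusted p = 0.688) and 7142 ± 468 against 5221 ± 719 CPM for adhP (adjusted p = 0.109). ZMO1116, ZMO1696, ZMO1885 and phoU had adjusted p of 0.803, 0.0926, 0.159 and 0.155.

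The list of ribosomal proteins was called as lower under vanillin (camera adjusted p = 8.40e-06, and 0.498 with an estimated correlation). The abundant small RNA rnpB stood lower beside it without overlap, at 10282 ± 1373 against 19042 ± 4648 CPM, and was not called (adjusted p = 0.0828). Of 57, rpsJ, rpsD and rplS (523 ± 2.41 from 736 ± 41.6 CPM) fell and none rose, with 12 falling when adjusted over the list alone. The Entner-Doudoroff and ethanol pathway (adjusted p = 0.0122) and ATP synthase (adjusted p = 0.0471) were called as higher with none of their 13 and 9 genes called, nor when adjusted over the lists alone. In the pathway, pgl stood at 1341 ± 58.4 against 1114 ± 103 CPM, glf at 10036 ± 922 against 7922 ± 1305 CPM. The ATP synthase subunit ZMO0242 stood at 2181 ± 266 against 1752 ± 150 CPM and ZMO0668 at 3488 ± 172 against 2596 ± 532 CPM. The rRNA list was higher as well (adjusted p = 0.0317), with 1 gene of 5 called, ZMOr005 at 93.5 ± 59.6 against 11.2 ± 3.17 CPM, and 2 adjusted over the list alone. With an estimated correlation the adjusted p was 0.633 for rRNA and 0.960 for the pathway and ATP synthase. Without the 2 libraries that stood apart, 43 ribosomal protein genes fell and none rose, and the pathway and ATP synthase lists were not called (camera adjusted p = 0.203 and 0.387). Amino acid biosynthesis was then called as lower (3 rose and 25 fell of 63, adjusted p = 0.00356). Two-component systems (7 of 24 rose and none fell) and phage and mobile elements (7 rose and 1 fell of 13) were called as higher, and rRNA still was (4 of 5 rose; 0.0252 for each of these 3). With an estimated correlation no list passed there either (0.197 for ribosomal proteins and 0.656 for the other 4).

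Without those 2 libraries, 562 genes were called under vanillin, 283 higher and 279 lower. The count of 50 became 5 or 7 without vector replicate 2 or 3 and 5, 6 or 5 without ZMO1162 replicate 1, 2 or 3, and upper-quartile scaling called 24 higher of 59 (40.7%, against 58% with TMM). It became 5 with the replicate block, 6 in a fit of only the 6 libraries compared, 30 by limma on FPKM, 83 with transcript-level counts, 169 in the fit of all 18 libraries, 221 by DESeq2 and 842 by voom with sample quality weights. Between the groups, 616 genes (35.1%) had no overlap, against 10% by chance.

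**Figure D2:**
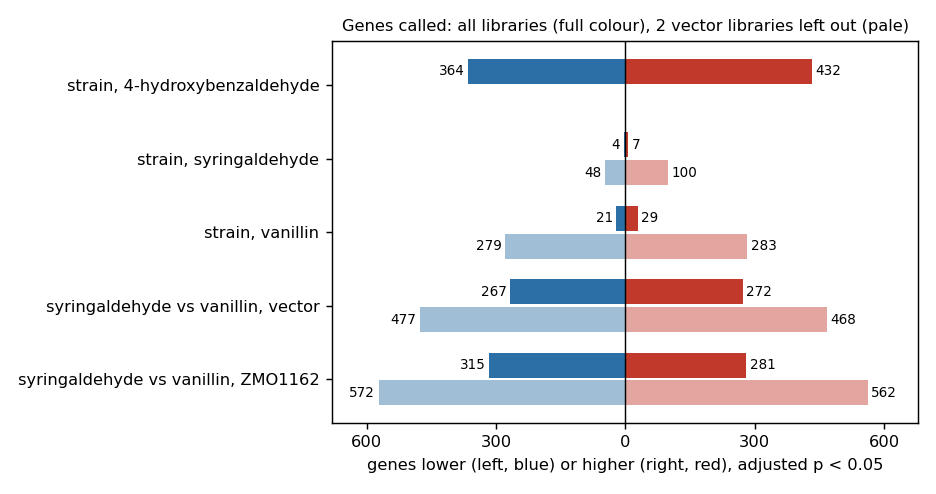
Number of genes with adjusted p below 0.05 in each comparison, higher to the right and lower to the left, with all libraries (full colour) and without 2 vector libraries that stood apart (pale; these are not part of the 4-hydroxybenzaldehyde comparison). Under vanillin the count went from 29 higher and 21 lower to 283 higher and 279 lower.

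**Figure D3:**
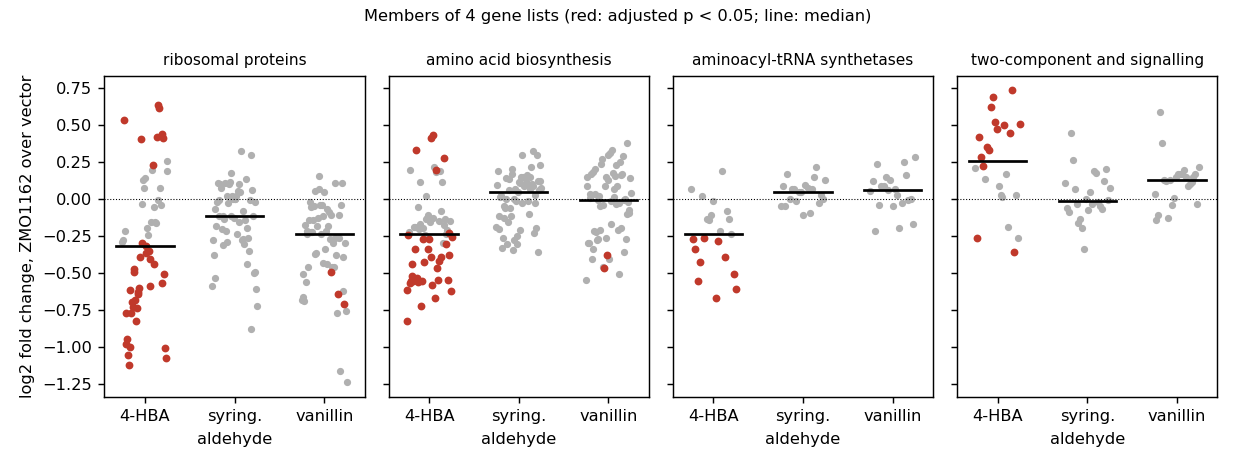
Log2 fold change of the ZMO1162 strain over the vector strain for each member of 4 gene lists under 4-hydroxybenzaldehyde (4-HBA), syringaldehyde (syring.) and vanillin, in order of locus tag, with genes past the threshold in red and the list median as a line. The median of the ribosomal protein list was -0.32, -0.12 and -0.24.

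In the gene tables ZMO1784 and ZMO1782, both annotated as hypothetical proteins, had 0 counts in all 6 libraries of the ZMO1162 strain under syringaldehyde and vanillin. No other gene was at 0 in all 6 of these libraries, and both had counts in each of the other 12. ZMO1784 (positions 1826709 to 1827842, plus strand) stood at 245 ± 114 CPM in the vector strain under syringaldehyde and at 185 ± 63.7 CPM under vanillin, and its counts there ranged from 1510 to 5512 per library. Against a floor of 3 counts per library it was at least 737-fold lower under syringaldehyde and at least 648-fold lower under vanillin (edgeR adjusted p = 8.06e-04 and 0.00136). Without the 2 vector libraries that stood apart, these bounds were 540.5-fold and 519.6-fold. Under 4-hydroxybenzaldehyde the same gene rose in the ZMO1162 strain, to 245 ± 51.7 from 151 ± 2.85 CPM (1.62-fold, adjusted p = 0.00674). ZMO1782 (positions 1826278 to 1826520), singled out after its values were seen, was at least 22-fold lower under syringaldehyde and at least 28.2-fold lower under vanillin by the gene tables alone. The bound under syringaldehyde rests on vector replicate 3, which stood apart, and is 12.9-fold without it. In the transcript tables ZMO1784 was also at 0, but ZMO1782 had 126 to 263 counts in each of these 6 libraries and kept 0.276 and 0.298 of the vector level, so the bounds for ZMO1782 do not hold there. ZMO1785 (positions 1828068 to 1828736, minus strand), a mechanosensitive ion channel family protein, fell to 7.23 ± 0.542 from 47.3 ± 11.7 CPM under syringaldehyde (6.55-fold, adjusted p = 1.80e-04) and to 13.0 ± 3.25 from 44.2 ± 7.25 CPM under vanillin (3.39-fold, adjusted p = 0.00359). ZMO1781, on the other side and also annotated as a mechanosensitive ion channel, and ZMO1786 kept 1.26 and 0.996 of the vector level under syringaldehyde and stood at 1.69 and 1.1 times that level under vanillin. The transcript tables held unusually many counts for ZMO1781, ZMO1782 and ZMO1785 (7.27, 7.26 and 7.02 times the gene tables, against a median of 3.89), so the gene-level values of these 3 genes are less sure than those of ZMO1784 (3.83 times).

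**Figure D4:**
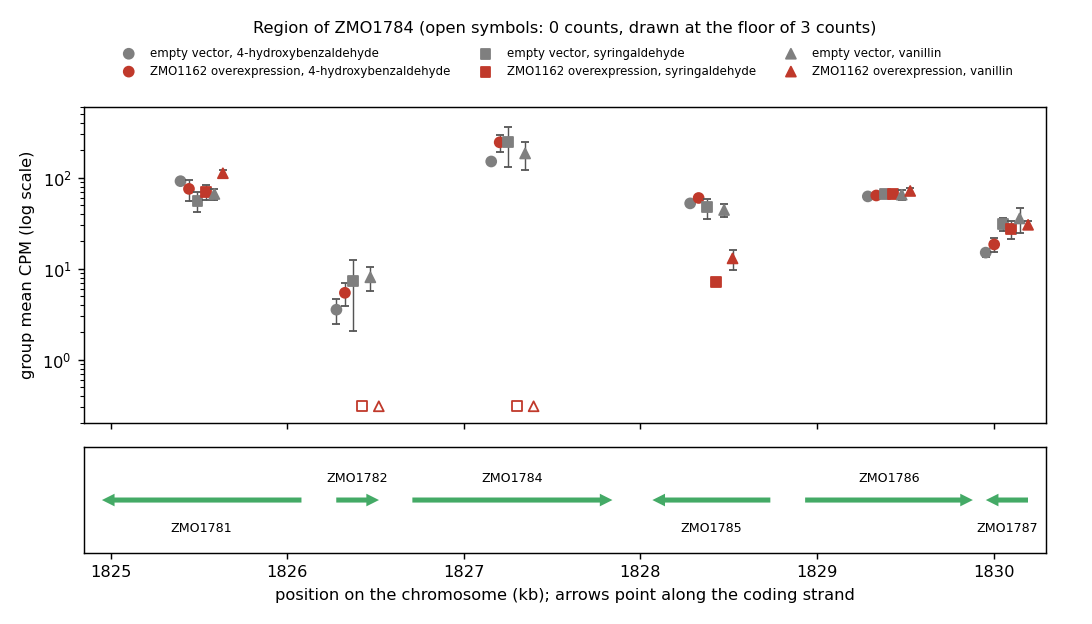
Mean CPM (log axis, SD as bars, n = 3) of the genes around ZMO1784 in the 6 groups, above the position and coding strand of each gene. ZMO1782 and ZMO1784 had 0 counts in the gene tables in the ZMO1162 strain under syringaldehyde and vanillin (open symbols, drawn at the floor of 3 counts) and were present in the other 4 groups.

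The calls of the strain effects under the 3 aldehydes overlapped. The genes ZMO1334, ZMO1344, ZMO1373, ZMO1892, ZMO0022 and ZMO1162 rose under all 3 aldehydes, and none fell under all 3. ZMO1373 was 1.90-fold, 1.59-fold and 1.58-fold higher under 4-hydroxybenzaldehyde, syringaldehyde and vanillin, and ZMO1344 was 1.38-fold, 1.34-fold and 1.47-fold higher. Without the 2 libraries that stood apart, 62 genes rose and 16 fell under all 3, and with the replicate block 1 rose. Rises under 4-hydroxybenzaldehyde and vanillin shared 19 genes against 7.16 for independent lists (one-sided Fisher exact test, adjusted p = 4.88e-06), and falls 9 against 4.37 (adjusted p = 0.0195). All 7 rises under syringaldehyde were also rises under 4-hydroxybenzaldehyde (1.73 by independent lists, adjusted p = 6.46e-05), while the 4 falls shared none with all libraries. Syringaldehyde and vanillin shared 6 rises and 3 falls (0.12 and 0.05 by independent lists, adjusted p = 1.63e-10 and 7.83e-06). The 3 shared falls were ZMO1782, ZMO1784 and ZMO1785, which lie side by side. ZMO1162, the overexpressed gene, is among the shared rises of every pair. The test counts such genes as independent, which can make its p-values too small. No libraries were shared between these comparisons, but those under syringaldehyde and vanillin came from 1 fit. Each of their vector groups also held 1 of the 2 libraries that stood apart in a shared way (Spearman 0.955). The adjustment covers 12 tests of overlap, 6 of them without the 2 libraries that stood apart. In those 6, rises and falls under 4-hydroxybenzaldehyde shared 77 and 26 genes with syringaldehyde (24.69 and 9.98 by independent lists, adjusted p = 2.15e-29 and 4.18e-07) and 176 and 145 with vanillin (69.86 and 57.62, adjusted p = 4.36e-49 and 1.13e-37). Syringaldehyde and vanillin then shared 76 and 32 (16.13 and 7.63, adjusted p = 9.54e-43 and 2.83e-15). The 2 libraries were left out after seeing the data. Their deviations ran along the strain effect under 4-hydroxybenzaldehyde (Spearman 0.469 and 0.561 across genes). Leaving them out therefore moves the other strain effects towards that one, and the larger overlaps with 4-hydroxybenzaldehyde cannot be told apart from this.

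The log2 changes were also correlated across genes, which are not independent replicates, leaving out ZMO1162 and the genes at 0, ZMO1782 and ZMO1784, since their large values move Pearson's r. Those under 4-hydroxybenzaldehyde correlated at 0.189 (Spearman 0.112) with syringaldehyde and at 0.231 (0.227) with vanillin. Those under syringaldehyde and vanillin, which also share a set of libraries, correlated at 0.782 (0.774), so aldehyde and set cannot be told apart here. The values became 0.592 (0.609), 0.548 (0.606) and 0.701 (0.715) without the 2 libraries. The rise in the correlations with 4-hydroxybenzaldehyde decides nothing, because the deviations of these libraries themselves ran along that strain effect. With the 3 genes included, Pearson's r was 0.098, 0.147 and 0.914.

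The strain effects under the 3 aldehydes, which differ by methoxy groups, were also compared by tests of their difference. Between syringaldehyde and vanillin, 0 genes differed by edgeR (23 at an unadjusted p below 0.05), 0 by DESeq2 and 34 by voom with sample quality weights, which was chosen after seeing the data. For 1464 of 1755 genes (83.4%) the 95% interval of the difference lay within 1 log2 unit either way, and the median distance from the estimate to a bound was 0.47. Ribosomal proteins were higher in this difference (camera adjusted p = 2.07e-06), and oxidative stress (adjusted p = 0.00707) and flagella (adjusted p = 0.0195) lower, with none of their genes called, nor when adjusted over the lists alone. Each had an adjusted p = 0.282 with an estimated correlation.

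The 4-hydroxybenzaldehyde libraries are a set of their own, apart from that of the other aldehydes. Only a set effect that is alike in both strains cancels in the next tests, so aldehyde and set cannot be told apart. Between 4-hydroxybenzaldehyde and vanillin, the strain effect differed for 22 of 1755 genes, 13 with a higher and 9 with a lower value under 4-hydroxybenzaldehyde. Among the higher were ZMO1785 (log2 1.96, SE 0.26), ZMO0934 (1.15), ZMO0378 (1.08) and rplY (0.81). Among the lower were ZMO1417 (-1.10), ZMO1754 (-1.0, SE 0.15, adjusted p = 0.00223), the metallopeptidase ZMO1776 (-0.99), ldhA (-0.96) and the sugar transporter ZMO0293 (-0.86). Between 4-hydroxybenzaldehyde and syringaldehyde, 6 genes differed, 4 higher and 2 lower. These included ZMO1785 (2.89, SE 0.27), the siroheme synthase gene cysG (0.69), the phosphate-binding protein gene pstS (-0.92) and ldhA (-0.88). With all libraries, ZMO1784 differed in both, by at least 10.04 and 10.22 log2 units, since it was at 0 in the ZMO1162 strain under vanillin and syringaldehyde. Both bounds would be lower without the 2 vector libraries that stood apart. The 95% interval lay within 1 log2 unit for 73.2% and 72.7% of genes.

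The lists named next were called at the preset correlation only, with an adjusted p of 0.959 each for vanillin and 0.660 each for syringaldehyde with an estimated correlation. The Entner-Doudoroff and ethanol pathway (camera adjusted p = 6.64e-04), ATP synthase (0.00157), aminoacyl-tRNA synthetases (0.00511) and amino acid biosynthesis (0.00582) were lower in the effect under 4-hydroxybenzaldehyde than under vanillin, with none of their genes called, nor when adjusted over the lists alone. Aldehyde and alcohol oxidoreductases were lower too, with 2 of 33 genes called (0.0187; 1 higher and 4 lower adjusted over the list alone). Amino acid biosynthesis and oxidoreductases were not called without the 2 libraries that stood apart (0.0878 each). Against syringaldehyde the lower lists were amino acid biosynthesis (2.59e-04), aminoacyl-tRNA synthetases (0.00281), the Entner-Doudoroff and ethanol pathway (0.00281), ATP synthase (0.00486), multidrug efflux and nucleotide synthesis (0.0462 each). Sigma factors and regulators were higher (0.0462), and in these lists no gene was called, with 3 of multidrug efflux lower when adjusted over the list alone. Without those 2 libraries, multidrug efflux (0.0832), nucleotide synthesis (0.239) and regulators (0.0611) were not called.

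Without the 2 libraries that stood apart, the counts were 136 for vanillin and 44 for syringaldehyde. They were 7 and 2 with the replicate block, 101 and 67 by DESeq2 and 568 and 603 by voom with sample quality weights, and against vanillin 34 with transcript-level counts and 38 with upper-quartile factors. The count of 22 became 136 without ZMO1162 4-hydroxybenzaldehyde replicate 2, 8 without ZMO1162 4-hydroxybenzaldehyde replicate 1, vector 4-hydroxybenzaldehyde replicate 1, vector vanillin replicate 1 or ZMO1162 vanillin replicate 1 or 2, 9 without ZMO1162 4-hydroxybenzaldehyde replicate 3, 12 without vector replicate 3 of either aldehyde, and 13 without vector 4-hydroxybenzaldehyde replicate 2 or ZMO1162 vanillin replicate 3. The count of 6 became 108 without ZMO1162 4-hydroxybenzaldehyde replicate 2, and 3 or 10 without ZMO1162 syringaldehyde replicate 2 or 3.

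Syringaldehyde and vanillin, which differ by 1 methoxy group, were compared directly within each strain. Their doses are not in the labels and may differ. In the vector strain 272 genes were higher and 267 lower under syringaldehyde, and in the ZMO1162 strain 281 were higher and 315 lower, of 1755 tested. The MFS transporter ZMO1457 was 4.93-fold higher in the vector strain (146 ± 26.8 against 29.5 ± 7.48 CPM, log2 2.30, SE 0.18, adjusted p = 1.48e-05) and 7.13-fold higher in the ZMO1162 strain (219 ± 10.9 against 30.7 ± 2.75 CPM). The methionine synthase gene metE stood at 4017 ± 1155 against 930 ± 251 CPM in the vector strain (4.32-fold, adjusted p = 1.32e-04) and at 4833 ± 396 against 1223 ± 45.8 CPM in the ZMO1162 strain (3.95-fold). The methionine adenosyltransferase gene metK was 3.15-fold higher in the vector strain. The list of sulfur assimilation and cysteine and methionine synthesis, which holds both, was not called (7 higher and 5 lower of 23 in the vector strain, camera adjusted p = 0.175, and 8 and 5 in the ZMO1162 strain, 0.196; 8 and 5 in each adjusted over the list alone). The TonB-dependent receptor ZMO0979 was 3.79-fold and 3.46-fold higher and ZMO0095 3.76-fold and 3.22-fold higher in the vector and ZMO1162 strains, and the metallophosphoesterase ZMO0131 3.0-fold higher in the ZMO1162 strain.

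The periplasmic adaptor of an RND efflux system, ZMO0282, was higher under vanillin. Its level was 3088 ± 385 against 1022 ± 203 CPM under syringaldehyde in the vector strain (3.02-fold, log2 -1.60, SE 0.16, adjusted p = 7.47e-05) and 3614 ± 209 against 1154 ± 130 CPM in the ZMO1162 strain (3.13-fold). The HlyD family adaptor ZMO0801 (200 ± 22.4 against 67.4 ± 2.22 CPM, 2.97-fold), the AraC family regulator ZMO1380 (3.11-fold), ZMO0931 (2.96-fold) and the monooxygenase ZMO1780 (2.91-fold) were also higher under vanillin in the vector strain. In the ZMO1162 strain the glucose 1-dehydrogenase ZMO1578 (3.22-fold), ZMO1780 (3.15-fold), ZMO1864 (3.02-fold) and the arginase family protein ZMO0432 (2.85-fold) followed the same direction. ZMO1162 itself was not called (adjusted p = 0.358 in the vector strain and 0.588 in the ZMO1162 strain).

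**Figure D5:**
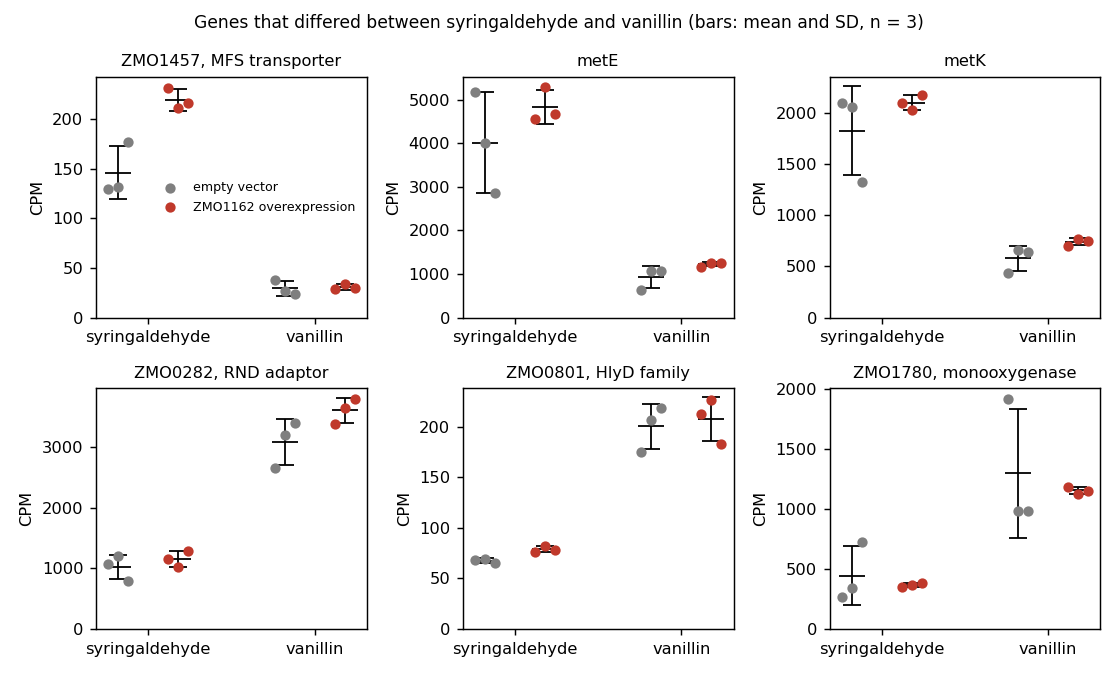
CPM of 6 genes that differed between syringaldehyde and vanillin in each library of the vector and ZMO1162 strains, with mean and SD of 3 libraries. The transporter ZMO1457, metE and metK were higher under syringaldehyde, and ZMO0282, ZMO0801 and ZMO1780 under vanillin.

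Gene lists were called between the aldehydes at the preset correlation, and none passed with an estimated correlation (adjusted p = 0.178 to 0.720 in the vector strain and 0.109 to 0.700 in the ZMO1162 strain). Signs of RNA quality, in CPM of unscaled totals, moved with the aldehyde in the 4 vector libraries that did not stand apart. In these the rRNA genes summed to 160.9 and 145 under syringaldehyde against 83.8 and 87.9 under vanillin, and rnpB stood at 10930.7 and 10447.1 against 17645.5 and 14110.6. The 2 that stood apart had 20.4 (syringaldehyde) and 42.7 (vanillin) for rRNA and 24201.5 and 29556 for rnpB. In the ZMO1162 strain the ranges overlapped, 204.9 to 268.1 against 160.3 to 452.5 for rRNA and 9354.3 to 10599.2 against 8430.1 to 10933 for rnpB. The rRNA list was not called in either strain (camera adjusted p = 0.730 and 0.779).

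Of 33 aldehyde and alcohol oxidoreductases, 16 were lower and 1 higher under syringaldehyde than under vanillin in the vector strain (camera adjusted p = 4.88e-06) and 19 lower and none higher in the ZMO1162 strain (6.65e-07). The examples from the lists named here were chosen after their values were seen: ZMO0101 (log2 -1.06 in the vector strain and -1.20 in the ZMO1162 strain), the aldo/keto reductase ZMO0976 (-1.14 and -1.10) and the alkene reductase ZMO1885 (-1.19 and -1.03). Genes of oxidative stress and thiol redox were lower too (12 lower and 2 higher of 32, adjusted p = 0.00196, and 16 lower and 1 higher, 1.29e-04). Among them were gorA (-0.71 and -0.95), the superoxide dismutase ZMO1060 (-0.81 and -0.95) and the catalase ZMO0918 (-0.51 and -0.72). Chaperones and heat shock proteases were lower (5 lower and 1 higher of 22, adjusted p = 0.0108, and 9 lower and 1 higher, 0.00370), with the protease gene lon at -0.79 and -0.84. The member that was higher, hemW, serves heme insertion. Of 23 genes of nitrogen fixation and ammonium use, 6 and 8 were lower and 1 higher (adjusted p = 0.0373 and 0.0241), with the nitrogenase iron protein gene nifH at -1.25 and -1.49.

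Ribosomal protein genes were higher under syringaldehyde, 21 of 57 in the vector strain (adjusted p = 1.07e-06) and 29 in the ZMO1162 strain (4.49e-10), with none lower and rplM at 0.54 and 0.86 on the log2 scale. Among the genes counted was rimO, which modifies a ribosomal protein (0.63 and 0.66). Genes of hopanoid and isoprenoid synthesis, whose products are membrane lipids of this bacterium, were higher as well (9 higher and 1 lower of 16, adjusted p = 2.13e-04, and 8 higher, 2.45e-04), with squalene-hopene cyclase, shc (ZMO0872), at 1.07 and 0.97. Nucleotide synthesis (5 and 8 of 24 higher, none lower, adjusted p = 0.0134 and 0.00428, with guaB at 0.94 and 1.01) and translation factors (6 and 5 of 18 higher, none lower, adjusted p = 0.0108 and 0.0160) were higher in both strains. In the ZMO1162 strain cell envelope genes were higher (10 higher and 1 lower of 40, adjusted p = 0.0338) and ATP synthase genes lower (3 of 9, adjusted p = 0.0338). Adjusted over the lists alone, the counts of lower genes in the vector and ZMO1162 strains were 17 and 20 for oxidoreductases, 13 and 20 for oxidative stress, 6 and 11 for chaperones and 6 and 8 for nitrogen. The counts of higher genes were 21 and 31 for ribosomal proteins, 12 and 10 for hopanoids, 5 and 8 for nucleotides and 6 and 5 for translation factors, and in the ZMO1162 strain 9 for the cell envelope, with 3 lower for ATP synthase.

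Without the 2 libraries that stood apart, 945 genes were called in the vector strain and 1134 in the ZMO1162 strain, and a fit of only the 6 libraries compared called 228 and 1126. Without them the pathway was also called as lower in both strains (camera adjusted p = 0.0402 and 0.00876), and in the vector strain ATP synthase as lower (0.00632) and sulfur genes as higher (0.0473), none of them with an estimated correlation. Between the aldehydes, 607 genes (34.6%) in the vector strain and 1205 (68.7%) in the ZMO1162 strain had no overlap, against 10% by chance for 3 against 3.

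With all libraries, the remaining lists were not called in the strain comparisons, with camera adjusted p from 0.0558 to 0.988 under 4-hydroxybenzaldehyde, from 0.0974 to 0.921 under syringaldehyde and from 0.0920 to 0.958 under vanillin. Under 4-hydroxybenzaldehyde members of these lists were called, but so were 45.49% of all tested genes, and such counts alone do not set a list apart. There, 18 rose and 5 fell of 56 sigma factors and regulators, 15 and 6 of 40 genes of flagella and chemotaxis, 14 and 5 of 42 TonB receptors and iron uptake genes, and 13 and 5 of 32 genes of oxidative stress and thiol redox. In transport and the envelope, 9 rose and 7 fell of 53 ABC and MFS transporters, 4 and 8 of 25 multidrug efflux genes and 7 and 8 of 40 cell envelope genes. In metabolism, 4 rose and 10 fell of 24 nucleotide synthesis genes, 4 and 5 of 23 sulfur genes, 3 and 5 of 23 nitrogen genes, 1 and 7 of 26 respiratory chain genes, 1 and 3 of 14 fatty acid genes, 1 and 2 of 16 hopanoid genes and 0 and 3 of 9 ATP synthase genes. The remaining counts were 5 and 6 of 22 chaperones, 3 and 8 of 18 translation factors, 4 and 4 of 21 DNA repair genes, 4 and 1 of 13 phage and mobile elements, and 3 and 1 of 10 genes of secretion, pili and toxins. Adjusted over each list alone, 4 rose and 4 fell of the ABC and MFS transporters, 3 and 1 of the DNA repair genes and 0 and 0 of the ATP synthase genes, and the other counts here differed by at most 2. Under vanillin, with all libraries, 3 oxidoreductases rose and 0 fell (4 and 0 adjusted over the list alone), and 0 amino acid biosynthesis genes rose and 2 fell (2 and 12 adjusted over the list alone). With the 2 libraries left out, 8 rose and 4 fell of the 33 oxidoreductases, 10 and 3 of the TonB receptors and iron uptake genes and 14 and 7 of the genes of flagella and chemotaxis under vanillin, and none of these 3 lists was called by camera (adjusted p = 0.597, 0.252 and 0.319).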

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

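All tests of explanations in this part were chosen only after the results were seen, apart from the counts over other splits of the libraries, which were planned. The genes below were singled out because the strain effect itself differed between aldehydes in an edgeR test of the difference. All these differences are from 4-hydroxybenzaldehyde, whose libraries are a set of their own, so aldehyde and set cannot be told apart. Between 4-hydroxybenzaldehyde and vanillin these were ZMO1784 (at least 10.04 log2 units), ZMO1785 (1.96), ZMO0934 (1.15), ZMO0378 (1.08), rplY (ZMO1910, 0.81), ZMO1417 (-1.1), ZMO1754 (-1.0), ZMO1776 (-0.99), ldhA (ZMO1237, -0.96) and ZMO0293 (-0.86). Between 4-hydroxybenzaldehyde and syringaldehyde they were ZMO1784 (at least 10.22), ZMO1785 (2.89), cysG (ZMO0006, 0.69), pstS (ZMO1047, -0.92) and ldhA (-0.88). The bounds for ZMO1784 were taken with all libraries.

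In the gene table ZMO1784 and ZMO1782 had 0 counts in the 6 ZMO1162 libraries under syringaldehyde and vanillin. Repression by the higher ZMO1162 level alone is argued against by the ZMO1162 strain under 4-hydroxybenzaldehyde, where ZMO1162 stood 22.3-fold over the vector strain, against 9.41- and 13.1-fold under syringaldehyde and vanillin, and the lowest ratio of ZMO1784 in a library to the vector mean was 1.385. Loss of shared reads in the gene table alone is argued against by the transcript table, where ZMO1784 was also at 0 and ZMO1782 kept at most 0.298 of the vector level. A candidate explanation is a deletion of ZMO1784 in the ZMO1162 culture used with these aldehydes: of ZMO1781 and ZMO1786, the lowest ratio to the vector level was 0.996. The transcript table holds 126 to 263 counts of ZMO1782 in each of these libraries, none of which the gene table gives to it. How either table assigns such reads is not known, so these counts decide nothing about a deletion of ZMO1782. Its fall and that of ZMO1785 stay open. The deletion stays a hypothesis, since no sequence reads or genome were analysed here, and an effect of ZMO1162 that needs a methoxylated aldehyde was not tested.

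Vector syringaldehyde replicate 3 and vector vanillin replicate 1 stood apart from their groups in a shared way, with a Spearman correlation of 0.955 between their deviations across 1734 genes, which are not independent replicates. An exchange of their labels is argued against by genes that differ between the aldehydes, on which they lay at 0.767 and 1.19 of the way to their own aldehyde. Gene length accounted for at most 7.6% of the variance of the deviations. Genomic DNA, which adds the same FPKM to every gene, is argued against as the main cause, since bins of the FPKM in the other libraries took up at most 19.8% of the variance over all genes. DNA as a smaller part stays open, since the percent of counts outside the gene table was highest in these 2 libraries (0.0821 and 0.16, against at most 0.0579 in the others). The FPKM below which the lowest 5% of genes lay was also highest there (26.2 and 30.56, against at most 19.48). In them 257 and 224 genes lay at least 2-fold above their groups and 25 and 12 at least 2-fold below. Those above gained a median of 107.2 and 101.3 FPKM. What sets these libraries apart stays open, and no biological explanation was tested, since the labels give both the same growth conditions as their groups.

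Ribosomal protein genes were lower in the ZMO1162 strain under 4-hydroxybenzaldehyde and vanillin by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.679 and 0.498). A bias by gene length or expression level is argued against by matched lists, since the list lay at least 0.201 log2 units below the 2.5 percentile of 1000 lists matched for both. The vector vanillin library that stood apart is argued against as the cause under vanillin, since the list's median without the 2 such libraries was -0.347, and neither is part of the comparison under 4-hydroxybenzaldehyde. How much of the absolute fall comes from scaling stays open: the highest median under 4 scalings was -0.155, with total counts under 4-hydroxybenzaldehyde, against -0.321 with TMM. A scaling moves all genes alike and cannot make the gap between the list and other genes. What lowers the list stays open, since growth rate or growth phase at harvest may differ between the strains and was not measured here.

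Other splits of the libraries were counted for each result. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real split alone, 1 of 10, reached its own count of 796 under 4-hydroxybenzaldehyde, 11 under syringaldehyde and 50 under vanillin, with at most 0 genes in another split. In the comparison of aldehydes it was 1 of 10 for 539 in the vector strain, with 241 in the highest other split, which parted the 2 libraries that stood apart, and 1 of 10 for 596 in the ZMO1162 strain, with 0. For the difference between syringaldehyde and vanillin the real count was 0, which all 100 splits reach by definition, so they say nothing about chance; the highest had 197, the split that exchanges the strains under vanillin. For 4-hydroxybenzaldehyde minus vanillin, 3 of 100 splits reached 22 genes. All 3 are among the 8 splits that kept the strains under 4-hydroxybenzaldehyde and so hold that strain effect, and the 2 others called 395 and 195 genes. The real count does not stand out from these 8, so chance cannot be excluded. For 4-hydroxybenzaldehyde minus syringaldehyde, 6 of 100 reached 6 genes and the highest called 437, so chance cannot be excluded; the others that reached 6 also kept the strains under 4-hydroxybenzaldehyde. For genes that changed one way under all 3 aldehydes, 1 of 100 splits, the real one, reached 6 genes and the highest other had 0. This says nothing about chance, since any regrouping of the libraries of 1 aldehyde called 0 genes there and so could share none.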

How the results depend on the processing

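The analysis without the 2 libraries that stood apart, voom with sample quality weights and total counts without TMM were chosen only after the results were seen. No named gene changed direction where its value was past the threshold in the main run or in the alternative. Changes of sign between values past it in neither run were not counted. Of 2070 alternative values over 115 gene results, 1769 stayed on their side of the threshold, 264 were no longer past it and 37 passed it only there. ZMO1162 stayed past the threshold in every alternative run, with log2 changes of 4.41 to 4.64 under 4-hydroxybenzaldehyde, 3.07 to 3.52 under syringaldehyde and 3.55 to 3.99 under vanillin. Depth sets the floor of 3 counts, 0.235 to 0.399 CPM, and with it the bounds for genes at 0.

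Counts below are for the strain effect unless the aldehydes are compared, and the cause was not tested where a count moved, apart from the stricter threshold and the smaller sets of libraries. With an absolute log2 change of at least 1 the counts were 14 under 4-hydroxybenzaldehyde, 4 under syringaldehyde and 5 under vanillin, 7 and 3 for 4-hydroxybenzaldehyde minus vanillin and minus syringaldehyde, 50 and 73 for syringaldehyde against vanillin in the vector and ZMO1162 strains, and 1 shared by all 3 aldehydes. Without the 2 libraries that stood apart they were 148 under syringaldehyde, 562 under vanillin, 136 and 44 for the differences, 945 and 1134 between aldehydes, and 78 shared. Voom with sample quality weights gave 94, 842, 568, 603, 1091, 1225 and 47 for the same results, and 34 for syringaldehyde minus vanillin. DESeq2 gave 49 under syringaldehyde, 221 under vanillin, 101 and 67 for the differences and 25 shared. Limma on FPKM gave 5 under syringaldehyde and 30 under vanillin. Transcript-level counts gave 83 under vanillin and 34 for 4-hydroxybenzaldehyde minus vanillin, where upper-quartile factors gave 38. A fit of only the 6 libraries compared gave 3 under syringaldehyde, 6 under vanillin, and 228 and 1126 between aldehydes, and a fit of all 18 gave 413 under 4-hydroxybenzaldehyde and 169 under vanillin. With an estimated correlation, 0 lists were called in place of 4, 2 and 4 under the 3 aldehydes and 8 and 10 between aldehydes.

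The replicate block treats same-numbered libraries as paired across both strains, and across syringaldehyde and vanillin. With it, 3 genes were called under syringaldehyde and 5 under vanillin. It gave 7 and 2 for 4-hydroxybenzaldehyde minus vanillin and minus syringaldehyde, and 1 shared by all 3. The counts elsewhere were 801 under 4-hydroxybenzaldehyde and 442 and 506 between aldehydes. The block called 4, 2 and 4 lists under 4-hydroxybenzaldehyde, syringaldehyde and vanillin.

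Leaving out 1 library at a time gave 263 to 1070 genes under 4-hydroxybenzaldehyde, where the lowest counts were 263, 375 and 525 without vector replicate 1, 2 or 3 and 518 without ZMO1162 replicate 1. Under syringaldehyde it gave 3 to 6, with 3, 6 and 6 without vector replicate 1, 2 or 3 and 3, 5 and 4 without ZMO1162 replicate 1, 2 or 3. Under vanillin it gave 5 to 38, with 5 and 7 without vector replicate 2 or 3 and 5, 6 and 5 without ZMO1162 replicate 1, 2 or 3. For 4-hydroxybenzaldehyde minus vanillin it gave 8 to 136, with 136 without ZMO1162 4-hydroxybenzaldehyde replicate 2, 8 or 9 without its replicate 1 or 3, 8, 13 or 12 without vector 4-hydroxybenzaldehyde replicate 1, 2 or 3, 8 or 12 without vector vanillin replicate 1 or 3, and 8, 8 or 13 without ZMO1162 vanillin replicate 1, 2 or 3. ZMO1162 4-hydroxybenzaldehyde replicate 2 also gave the highest count, 108, for 4-hydroxybenzaldehyde minus syringaldehyde, where the range was 3 to 108, with 3 and 10 without ZMO1162 syringaldehyde replicate 2 or 3. Between aldehydes it gave 417 to 764 in the vector strain and 429 to 472 in the ZMO1162 strain, and 0 throughout for syringaldehyde minus vanillin.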

Other observations

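The tests of the phosphate genes below were chosen only after the results were seen, as was the analysis without the 2 libraries that stood apart. In that analysis, 62 genes rose and 16 fell in the ZMO1162 strain under all 3 aldehydes. The genes named here were chosen after their values were seen. Those that rose under all 3 included gshB, which makes glutathione, the glutathione S-transferase ZMO0935, msrA, which repairs oxidised methionine, bfr, which stores iron, both subunits of the integration host factor (ihfA and ZMO1801) and the EAL-domain protein ZMO0401. The fixed list of oxidative stress and thiol redox, with 32 genes, was not called: 5 rose and 5 fell under syringaldehyde (camera adjusted p = 0.842) and 6 rose and 1 fell under vanillin (0.170) in that analysis, and 13 rose and 5 fell under 4-hydroxybenzaldehyde (0.25). Those that fell under all 3 included the ribosomal protein genes rpsN, rpsH, rpsQ and rplX, the initiation factor gene infB, and serA and ZMO1684, which act in serine synthesis.

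In the 2 vector libraries that stood apart, several list medians moved alike relative to the other libraries of their groups. In vector syringaldehyde replicate 3 and vector vanillin replicate 1 the medians were 0.75 and 0.84 for TonB receptors and iron uptake, 0.63 and 0.59 for sigma factors and regulators, and -0.30 and -0.39 for the Entner-Doudoroff and ethanol pathway, on the log2 scale. They moved by different amounts for rRNA (-2.03 and -0.02) and for phage and mobile elements (0.29 and 0.63). The rnpB RNA stood at 24201.5 and 29556.0 CPM of unscaled totals, against at most 17645.5 in the other 16 libraries. The strain effect under 4-hydroxybenzaldehyde correlated with their deviations across 1732 genes, which are not independent replicates (Spearman 0.469 and 0.561, Pearson 0.407 and 0.527). Leaving these libraries out therefore moves the other strain effects towards that one, which bears on the genes shared by all aldehydes in that analysis.

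Since ZMO1162 lies next to phoU, a hypothesis was that its overexpression raises the genes of phosphate transport and signalling together. Under 4-hydroxybenzaldehyde 3 of 6 such genes were called as lower, which argues against it there: pstS fell by 0.741 (adjusted p = 0.00646), pstC by 0.266 (0.0471) and pstB by 0.291 (0.0293) on the log2 scale, and none was called as higher. Under syringaldehyde and vanillin the medians of 0.094 and -0.049 decide nothing, since members went both ways. Of the 6, phoU stood higher without overlap under 4-hydroxybenzaldehyde, syringaldehyde and vanillin (0.218, 0.29 and 0.374) but was not called (adjusted p = 0.0606, 0.468 and 0.155).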
